A study of Mus musculus with 2 samples.

How the data were processed

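Poly(A) RNA of eosinophils was sequenced from 2 independent sorts of cells positive for CCR3 and SiglecF, taken from the pooled bone marrow of untreated C57BL6J mice. The libraries were stranded and made with dUTP, per the labels' protocols. Both libraries belong to 1 group, and the labels describe no treatment or second cell type, so no comparison between conditions was made. The libraries are called sort 1 and sort 2 after the replicate numbers in their titles. How many mice went into each pool is not given in the sources used here.

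Reads were aligned with STAR 2.4.0c to the mouse build mm10, per the submitters' processing notes. The program that counted reads, its strand setting and its filters are not given in the sources used here. The authors deposited whole-number read counts for each group of RefSeq transcripts with a shared start and end. Beside them the authors deposited RPKM values, reads scaled by transcript length and by sequencing depth. For rows with 1 transcript the ratio of the count to the RPKM followed transcript length, and it implied a divisor of 40.4 in sort 1 and 40.5 in sort 2, in units of 1000000 reads. The counts summed to 10087743 and 9264150 reads, which is 24.9% and 22.9% of that divisor. RPKM values are therefore lower than values computed from the table's own total would be, by a similar factor in both libraries. Rows with several transcripts did not keep that ratio, so their counts may be rounded estimates of a split among transcripts. Coordinates are those of the deposited tables, on mm10.

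Each table had 26099 rows. Counts and RPKM values were summed over rows with the same gene symbol, which gave 23343 genes, of which 2060 came from several rows. Some rows named several genes that share transcripts, and these were kept as 1 entry under the joint name. The tables used older symbols for some genes, and these are printed as deposited, with Siglec5 for Siglecf, Sfpi1 for Spi1, Emr1 for Adgre1, Lilrb3 for Pirb and Gpr44 for Ptgdr2. No gene encoded by the mitochondrial genome was among the rows analysed here.

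The gene lists, the tests and the rule for naming genes were fixed before the data were examined. There were 31 lists, covering eosinophil genes, functions, sample quality and the other cell types that the gate could hold. A gene was called detected at an RPKM of at least 1 in both sorts. The level of a list was its median RPKM, and its percentile was taken among 10000 random lists of the same size drawn from all genes. The shift of a list was the median log2 ratio of sort 2 to sort 1, computed from TMM-scaled CPM with a prior count of 2. Its percentile was taken among 10000 random lists matched on mean expression, each member being replaced by 1 of the 200 genes nearest to it. A shift was called outside the random lists when it lay beyond their central 95%. With 31 lists of unrelated genes, chance would put 1.55 outside. Members of a list may vary together and some lists share members, so the number for these lists may be higher.

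Genes differing between the sorts were sought with an exact two-sided binomial test on the counts of the 2 libraries, given TMM-scaled library sizes. Adjustment was by Benjamini and Hochberg over genes with at least 10 reads in both libraries together, and a gene was called at an adjusted p under 0.05 and a fold of at least 2. This test compares the 2 libraries with sampling noise and not conditions, because each sort has 1 library. The quasi-likelihood test of edgeR could not be used with 1 group. The common dispersion of edgeR was estimated from both libraries as 1 group, and edgeR's exact test with that dispersion served as an alternative. The binomial test was tested on simulated data of these libraries. With sampling noise only, it called 99 of 100 genes changed 4-fold, 43 of 50 changed 2.5-fold and 2 of 12136 unchanged genes. With the estimated dispersion added, it called 619 of 12145 unchanged genes, or 5.10%.

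Named genes were the 25 with the highest mean RPKM, leaving out mitochondrial and ribosomal protein genes; the 4 highest members of each list, with every member for eosinophil lists; and the 10 genes with the largest fold each way among called genes with a mean of at least 50 reads. Of the genes this rule takes, 2 are not reported here. Shares of reads carry 95% Wilson intervals. Intervals and the limit of 3 reads that a count of 0 allows cover counting error only, since reads without molecular identifiers are not independent molecules.

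Alternatives chosen before the data were examined were other RPKM minimums, CPM in place of RPKM, other pseudocounts, list means in place of medians, DESeq2 size factors or total counts for scaling, other count filters, another fold, list shifts from the deposited RPKM values or from members with at least 10 reads, and leaving out each sort. A correction for transcript GC content was added after the data were seen. GC content came from GENCODE transcripts matched by RefSeq accession, available for 98.9% of the genes with at least 100 reads, and a lowess curve with a span of 0.3 was subtracted from the log2 ratios. Leaving out Rn45s, and Rn45s with the sex-linked genes, was also chosen after the data were seen. The work used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.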

Results

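Gene expression was measured in native bone marrow eosinophils, granulocytes that carry the chemokine receptor CCR3 and the lectin SiglecF, from 2 independent sorts of 1 group. The tables held 10087743 reads in sort 1 and 9264150 in sort 2. Values are given as mean RPKM ± SD with n = 2 sorts, or as the value of each sort. An SD from 2 libraries is itself imprecise.

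Of the 23343 genes, 7048 were detected in both sorts, 477 in sort 1 only and 333 in sort 2 only, while 7886 had no read in either. An RPKM of at least 10 in both sorts was reached by 1296 genes and of at least 100 by 66. Retnlg, a resistin-like secreted protein of granulocytes, had the highest mean at 2380 ± 83.5 RPKM (SD, n = 2). It was followed among the protein-coding genes by Ear1, an eosinophil-associated ribonuclease, at 1347 ± 163, Actb, cytoplasmic actin, at 1181 ± 244, and Prg2, the major basic protein of the eosinophil granule, at 1125 ± 303 (SD, n = 2). The nuclear noncoding RNA Malat1 had 1096 ± 74.7 RPKM. Next came S100a9, a calcium-binding protein of myeloid cells, at 797 ± 115, Alox15, the 12/15-lipoxygenase, at 758 ± 35.4, and B2m, the light chain of MHC class I, at 641 ± 120. The chemokine Ccl6 had 409 ± 9.10 RPKM and S100a8, the partner of S100a9, had 400 ± 2.38.

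Others among the 25 were S100a11, Cd24a, Arhgdib, Tmsb4x, Ear7, Pfn1, Itgam, Myadm, Ngp, Tyrobp, Sh3bgrl3, Zfp36, Srgn and the joint entry of Ear12 and Ear3. Rn45s, the ribosomal RNA precursor, was the exception to the agreement of these genes, with 3872 RPKM in sort 1 and 377 in sort 2. It was the 1 of the 25 called different between the sorts. Ribosomal protein genes, 84 in number, had median RPKM values of 24.3 and 18.2 and took 0.701% and 0.661% of the reads.

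**Figure D1:**
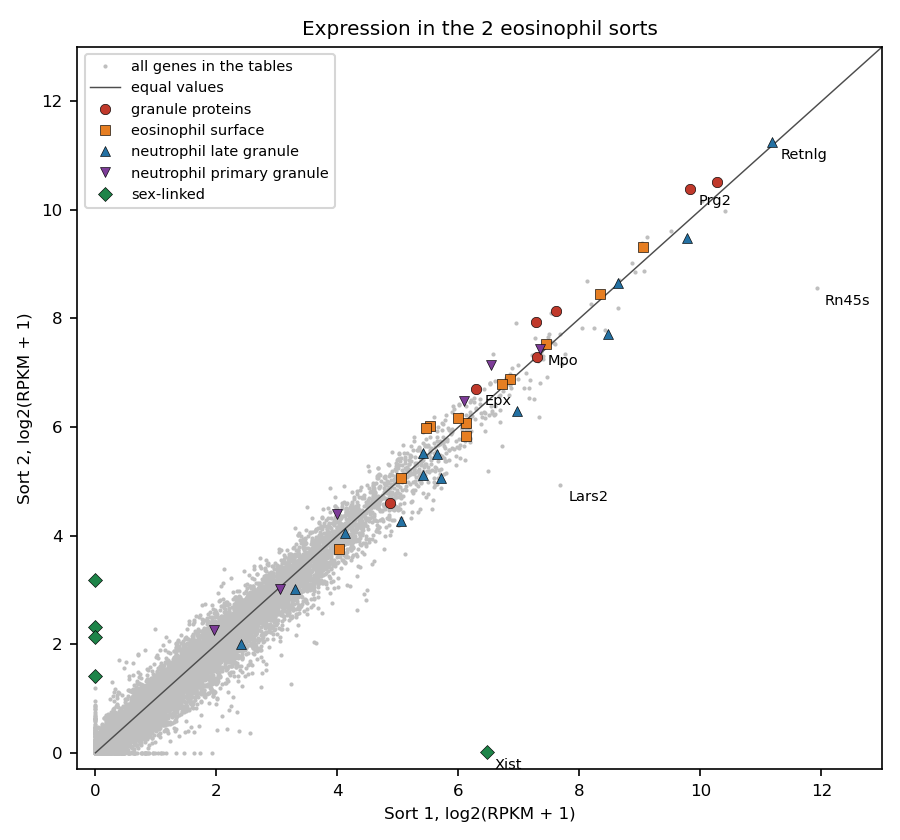
Expression of each gene in sort 1 (x axis) and sort 2 (y axis), both as log2(RPKM + 1), with members of 5 gene lists in colour and a line of equal values. Most genes lie near the line, while Rn45s and Xist lie below it and 4 Y-linked genes lie on the left edge.

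Granule protein transcripts were at high levels in both sorts. All 7 genes of the list were detected, with median RPKM values of 156 and 243, above every one of the random lists. Prg2 and Ear1 led, followed by Srgn, the proteoglycan that packs granule contents, at 239 ± 61.5, Ear6 at 199 ± 62.1, Ear2 at 155 ± 0.641, Epx, eosinophil peroxidase, at 90.5 ± 18.5, and Prg3, a homologue of Prg2, at 25.8 ± 3.47 (SD, n = 2). In the Ear family 6 of 10 entries were detected. The joint entry of Ear12 and Ear3 had 492 ± 36.4 RPKM, Ear7 had 345 ± 92.9 and Ear10 had 3.14 ± 0.142. Ear11 had 0.571 ± 0.403 RPKM, Ear5 had 1 read in sort 2, and Ear4 and Ear14 had no reads. These ribonucleases are near-identical copies, so the level of each member is uncertain.

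The surface molecules used to define eosinophils were all detected, with list medians of 68.8 RPKM in each sort. The sort markers themselves differed little between the sorts, with Ccr3 at 116 ± 2.34 RPKM and Siglec5, the SiglecF gene, at 32.2 ± 0.0656 (SD, n = 2). Higher levels than both were found for Cd24a at 582 ± 75.1 and the integrin subunits Itgam at 337 ± 20.4 and Itgb2 at 178 ± 7.13. The phosphatase Ptprc, or CD45, had 107 ± 4.18 RPKM. Cd44 had 67.8 ± 1.63 RPKM, Emr1, the F4/80 antigen, 66.6 ± 6.08, Lilrb3 62.4 ± 8.80, Itga4 54.3 ± 12.9, Il5ra, the interleukin-5 receptor subunit, 52.9 ± 13.6, and Cd9 13.8 ± 2.00. None of the 12 was called different between the sorts at a fold of 2, although 10 passed the adjusted p of the exact binomial test at any fold.

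Transcription factors of the lineage were expressed at lower levels, with 16 of 19 detected and medians of 4.35 and 4.13 RPKM. Sfpi1, the myeloid factor PU.1, had 49.9 ± 16.0 RPKM, Ikzf1 38.6 ± 0.301, Id2 24.0 ± 3.69, Trib1 20.5 ± 1.88, Stat6 20.1 ± 0.139 and Stat3 11.8 ± 1.19 (SD, n = 2). Cebpe, a factor of granulocyte maturation, had 8.41 ± 1.06 RPKM and Gata1, which is required for the eosinophil lineage, had 6.44 ± 0.800. Xbp1 had 4.28 ± 0.215, Stat5b 4.27 ± 0.108, Cebpb 3.18 ± 0.272, Runx1 3.07 ± 0.405, Gfi1 2.61 ± 0.856, Stat5a 2.02 ± 0.416, Gata2 1.99 ± 0.514 and Id1 1.77 ± 0.290. The 3 members below the minimum were Irf8 at 0.833 ± 0.0694, Cebpa at 0.537 ± 0.0320 and Zfpm1 at 0.430 ± 0.0420 RPKM.

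Among functional lists, those for the oxidative burst, lipid mediators and granule release were strongly represented. All 8 NADPH oxidase genes were detected, with medians of 62.2 and 57.4 RPKM, led by Ncf1 at 186 ± 2.06 and Cybb, the catalytic subunit, at 112 ± 2.62. Of the 12 lipid mediator genes 9 were detected, with medians of 9.70 and 9.08. Alox5ap, the 5-lipoxygenase activating protein, had 160 ± 11.1 RPKM, and Alox5 had 45.5 ± 0.206 (SD, n = 2). Fc and inhibitory receptors reached medians of 22.8 and 19.0 with 13 of 16 detected, led by the Fc receptor gamma chain Fcer1g at 170 ± 6.13 and Clec12a at 79.7 ± 10.8. The degranulation machinery had 14 of 15 detected and medians of 22.7 and 15.2, with Snap23 at 38.8 ± 0.359, Lamp1 at 38.2 ± 5.51 and Cd63 at 38.0 ± 12.9.

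Receptor lists held a few high members among many low ones. Of 30 cytokine receptors 20 were detected, with medians of 3.47 and 2.88 RPKM. Il17ra had 107 ± 7.25, Csf2ra, the alpha subunit for GM-CSF, 73.7 ± 14.8, and Csf2rb, the shared beta subunit, had 44.8 in sort 1 and 35.2 in sort 2. Of 20 chemoattractant receptors 11 were detected, with medians of 3.82 and 3.51. After Ccr3 came Cxcr4 at 39.8 ± 1.52, P2ry14 at 22.4 ± 6.24 and C3ar1 at 13.7 ± 1.94. Of 20 pattern recognition receptors 7 were detected, or 17 at a CPM of at least 1, with medians of 0.314 and 0.437. Tlr13 led with 11.3 ± 2.03 (SD, n = 2). Of 25 cytokines and chemokines 11 were detected, with medians of 0.748 and 0.858. Il4 had 15.3 ± 2.36 RPKM, Tgfb1 11.9 ± 2.21 and Il16 9.03 ± 0.160.

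All 20 genes of protein folding in the endoplasmic reticulum passed the minimum, with medians of 5.27 and 4.41 RPKM and the chaperone Hsp90b1 at 83.5 ± 11.0. Of 22 cell cycle genes 21 were detected, with medians of 2.79 and 2.88, including Mki67 at 29.8 ± 11.6 and Top2a at 13.1 ± 3.35 (SD, n = 2). The BCL2 family had 7 of 16 detected and medians of 1.16 and 0.911, and its leading member was the survival protein Mcl1 at 93.9 ± 12.5. The interferon response had 7 of 16 detected and medians of 1.72 and 0.880. Immediate early genes had 12 of 17 detected and medians of 4.12 and 3.24, with Zfp36 at 244 ± 25.3 and Dusp1 at 176 ± 32.7. Housekeeping genes had 12 of 13 detected and medians of 15.1 and 13.1, with Gapdh at 111 ± 7.92.

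**Figure D2:**
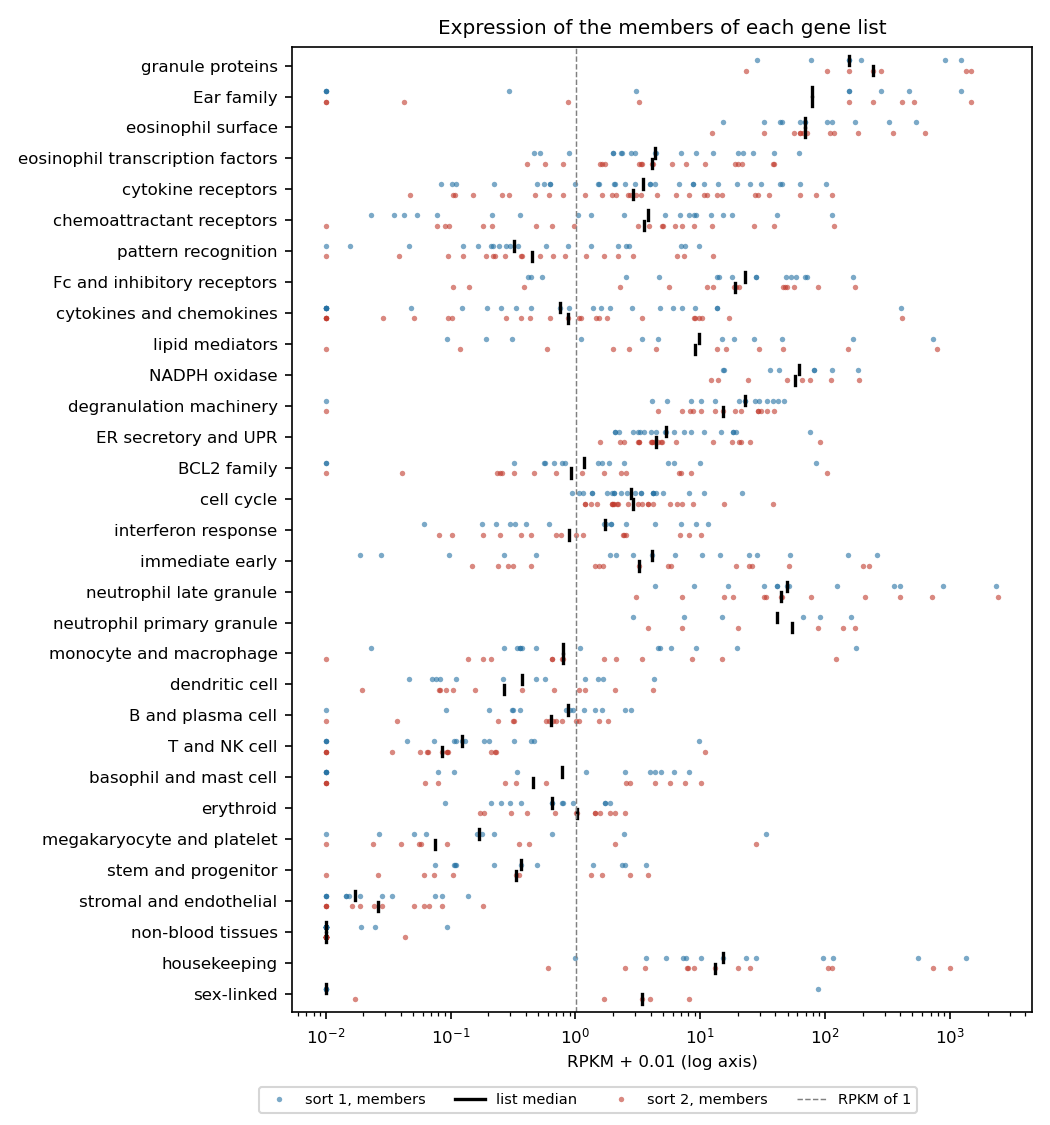
RPKM + 0.01 of each list member on a log axis, with sort 1 in blue, sort 2 in red and the list median as a black bar. The granule protein medians of 156 and 243 RPKM are the highest, and the 18 non-blood genes lie below an RPKM of 1.

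Markers of other cell types were compared with the eosinophil lists within each library. The lists hold different genes, so this comparison sets unlike transcripts side by side and does not measure the content of each cell type. Neutrophil genes were the abundant exception among the other cell types. Here late granule genes are a list of secondary granule genes and other markers of mature neutrophils. Primary granule genes are a list of genes of granulocyte-monocyte precursors, and not every member of either list encodes a granule protein. All 13 late granule genes were detected, with medians of 49.3 and 44.5 RPKM, and beside Retnlg, S100a9 and S100a8 they included Ngp, neutrophilic granule protein, at 353 in sort 1 and 210 in sort 2. All 6 primary granule genes were detected, with medians of 40.9 and 53.9, including Mpo, myeloperoxidase, at 167 ± 8.70, Igsf6 at 116 ± 34.1, Elane, neutrophil elastase, at 77.3 ± 14.8 and Ctsg, cathepsin G, at 17.5 ± 3.60 (SD, n = 2).

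Remaining cell types had medians of at most 1.01 RPKM. Their detected counts depended on the minimum, and at a CPM of at least 1 they were 12 for B and plasma cell, 12 for erythroid, 11 for monocyte and macrophage, 10 for dendritic cell, 7 for stem and progenitor, 4 for megakaryocyte and 3 for T and NK cell markers. Monocyte and macrophage markers had 6 of 14 detected and medians of 0.778 in both sorts, although Lyz2, lysozyme, had 148 ± 38.5 RPKM and Csf1r had 17.4 ± 3.37. Basophil and mast cell markers had 6 of 14 detected and medians of 0.773 and 0.448, led by Cpa3 at 8.10 ± 2.83 and Hdc at 7.88 ± 0.396. Dendritic cell markers had 4 of 12 detected and medians of 0.361 and 0.256, with Cd74 at 4.18 ± 0.0569. B and plasma cell markers had 3 of 14, or 5 in sort 1 alone, and medians of 0.868 and 0.632, with Cd79b at 2.29 ± 0.674. T and NK cell markers had 1 of 15, Nkg7 at 10.4 ± 0.839, and medians of 0.113 and 0.0750. Erythroid markers had 3 of 13, or 8 in sort 2 alone, and medians of 0.640 and 1.01, with Tfrc at 2.10 ± 0.535. Megakaryocyte markers had 2 of 10, of which the integrin subunit Itgb3 had 30.7 ± 3.99, and medians of 0.160 and 0.0657. Stem and progenitor markers had 4 of 11 and medians of 0.354 and 0.322, with Meis1 at 3.75 ± 0.119. No stromal or endothelial marker of 12 was detected, with medians of 0.00709 and 0.0162, and 38 and 58 reads in all. No gene of the 18 from non-blood tissues was detected, with 6 reads in sort 1 and 1 in sort 2.

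In each library the granule protein list and the eosinophil surface list lay above each of the 12 other lists, which gave 24 of 24 differences above 0 in both sorts. Because the lists hold different genes, these differences do not measure the purity of the sorts. On the log2(RPKM + 1) scale the granule protein median exceeded the late granule median by 2.03 ± 0.55 and the primary granule median by 2.37 ± 0.17 (SD, n = 2). The eosinophil surface median exceeded them by 0.54 ± 0.10 and 0.89 ± 0.28, and with list means in place of medians these differences were 0.28 and 1.46. The surface list holds genes that other leukocytes also express, such as Itgam, Itgb2, Ptprc and Cd44. Its margin over the neutrophil lists therefore does not measure eosinophil against neutrophil content. The smallest differences from the remaining cell types were 6.75 ± 0.24 for granule proteins and 5.26 ± 0.21 for the surface list, both against erythroid markers. With list means they were 6.01 and 4.66, both against monocyte and macrophage markers. With a pseudocount of 0.1 in place of 1 the differences from erythroid markers were 7.74 and 6.24, so their size depends on the pseudocount. An exact sign test of these differences over 2 libraries cannot give a two-sided p below 0.5, so none was made. Of the 31 lists, 16 had medians above the central 95% of random lists in both sorts. With random lists drawn from detected genes, 10 did.

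The sorts were close in overall profile and yet further apart than sampling noise. Across genes, which are not independent replicates, the Pearson correlation of log2(RPKM + 1) was 0.987 and the Spearman correlation 0.955. The chi-square of the counts was 968950 over 12347 genes, or 78.5 per gene, so the libraries were not the same library deposited again. This sum is weighted towards genes with many reads that differ, above all Rn45s with 914623 and 89209 reads. The value of 78.5 therefore does not describe a typical gene. The biological coefficient of variation, the square root of the edgeR common dispersion, was 0.232, and 0.231 without Rn45s. The 10 genes with most reads over both sorts together took 16.8% of sort 1 (95% Wilson interval 16.74 to 16.79) and 10.1% of sort 2 (10.05 to 10.09). They are not the top 10 of each sort, since Xist with 47487 reads in sort 1 is not among them. Rn45s alone took 9.07% and 0.963%, and with its reads left out of the total as well, the others among them held 8.47% and 9.19%.

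The genes with the largest difference between the sorts were Xist and 4 genes of the Y chromosome. Xist, the RNA that silences an X chromosome in females, had 47487 reads in sort 1 and 5 in sort 2. Kdm5d, Ddx3y, Eif2s3y and Uty had no reads in sort 1 and 756, 745, 583 and 355 in sort 2, at least 264, 260, 203 and 124-fold higher against a limit of 3 reads. Higher in sort 1 were also Rn45s by 9.81-fold, at chromosome 17 from 39842997 to 39848829, and Lars2, mitochondrial leucyl-tRNA synthetase, by 6.56-fold, with 204 and 29.6 RPKM, at chromosome 9 from 123366940 to 123462664. Rdh1, a retinol dehydrogenase, was 6.37-fold higher in sort 1 with 96 and 14 reads, and the scavenger receptor Cd163 4.41-fold higher with 163 and 35. Ddx49, Lmna, Asb14, Atxn7l2 and Sdc3 were 4.35 to 3.54-fold higher in sort 1. In sort 2, Smim1, with 129 reads and none in sort 1, was at least 45.0-fold higher. Rsl1, Prps1, Zmat1 and Slc4a1, the anion exchanger of red cells, were 3.76 to 3.10-fold higher.

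In total 970 of 12347 tested genes were called, 365 higher in sort 2 and 605 higher in sort 1, by the exact binomial test with Benjamini-Hochberg adjustment. At any fold 5360 genes, or 43.4%, passed the adjusted p. In simulated libraries with the estimated dispersion and no change, 5184 of 12145 genes, or 42.7%, did so. That dispersion was estimated from these same libraries, so it already holds the differences between them. The nearness of the simulated to the observed share is therefore no independent check, and the edgeR calls rest on the same dispersion. The edgeR exact test with the estimated dispersion called 33 genes, 16 higher in sort 2, and 766 had an unadjusted p under 0.05. The Y-linked genes, Xist, Rn45s, Lars2, Rdh1, Cd163 and Smim1 were among the 33, and Ddx49, Lmna, Asb14, Atxn7l2, Sdc3, Rsl1, Prps1, Zmat1 and Slc4a1 were not. Scaling by total counts gave 413 higher in sort 2 and 530 higher in sort 1.

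Of 371 tested members of the lists, each counted once, 38 were called, 17 higher in sort 2 and 21 higher in sort 1, beside 970 of all 12347 tested genes. The count adjusted over the list alone differed in 1 list, B and plasma cells, with 1 call in place of 2. Neither neutrophil list, nor the granule protein, surface, cell cycle or NADPH oxidase list, had a called member.

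The medians of 8 lists, the sex-linked list among them, lay outside those of matched random lists. Lists of unrelated genes would give 1.55 by chance, but members of a list may vary together and some lists share members. From the deposited RPKM values 12 lists lay outside, the Ear family, cytokines and chemokines, Fc and inhibitory receptors and housekeeping genes being added. Higher in sort 2 were granule proteins with a median log2 ratio of 0.49, primary granule genes with 0.46, erythroid markers with 0.49 and the cell cycle with 0.22. The sex-linked list had a median of 8.22, or 7.67 with the genes at 0 set to their bounds. Lower in sort 2 were late granule genes with -0.23, the degranulation machinery with -0.16, and monocyte and macrophage markers with -0.36. For granule proteins, 6 of 7 members had ratios above 0, Prg3 being the exception at -0.21. All 6 primary granule genes had ratios above 0, and 3 of 13 late granule genes did. These are descriptions of 2 libraries, and the ratios between them also followed transcript GC content as given next.

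Between-sort ratios followed the GC content of the transcripts. Across 8680 genes with at least 100 reads, the Spearman correlation of the log2 ratio of sort 2 to sort 1 with GC content was -0.54 and with length 0.143. The median log2 ratio was 0.35 in the tenth of genes with the lowest GC content and -0.35 in the tenth with the highest. After correction for this trend, 9 lists lay outside the random lists, 7 of them the same lists in the same direction. The monocyte and macrophage list, at percentile 2.24 before and 2.68 after, no longer did. Chemoattractant receptors, with a corrected median of -0.30, and immediate early genes, with 0.25, came to lie outside.

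**Figure D3:**
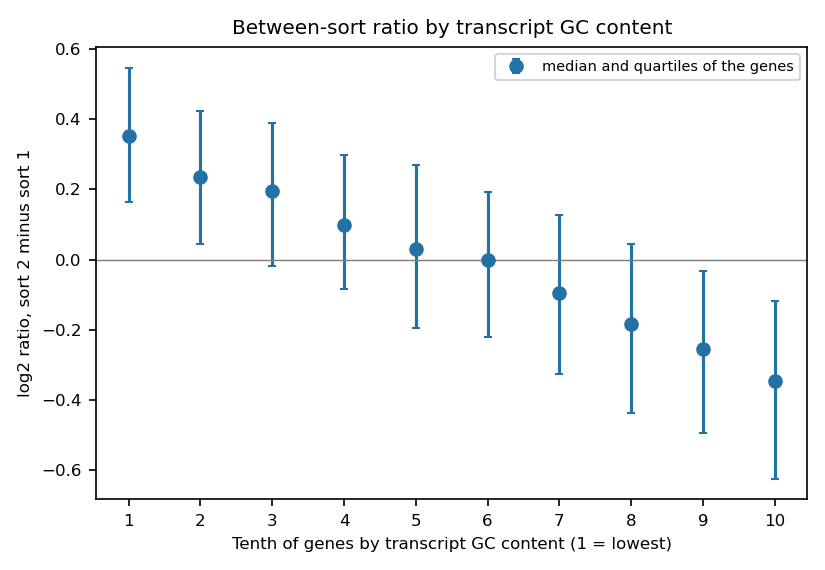
Median log2 ratio of sort 2 to sort 1 (points) with quartiles (bars) in 10 equal groups of genes ordered by transcript GC content, 868 genes in each. The median goes from 0.35 at the lowest GC content to -0.35 at the highest.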

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

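The GC correction and the settings without Rn45s or the sex-linked genes were chosen after the data were seen. Detected genes numbered 2700 at an RPKM minimum of 5 and 10936 at a CPM of 1, and 7381 to 7525 with either sort alone. The Pearson correlation was 0.984 with a pseudocount of 0.1 and 0.970 over genes detected in both sorts, and the coefficient of variation was 0.202 with a filter of 100 reads. For these the cause was not tested. Genes differing between the sorts numbered 2173 at a fold of 1.5 and 33 with the edgeR exact test. That test takes its allowance for variation beyond sampling noise from the same libraries that it compares. They numbered 973 with DESeq2 size factors, 991 without a count filter, 964 without Rn45s and the sex-linked genes, and 771 after GC correction, of which 657 were among the 970. Detected members of lists also moved by over 1.5 times. At an RPKM minimum of 5, 7 of 20 protein folding, 4 of 22 cell cycle, 8 of 19 transcription factor, 12 of 30 cytokine receptor and 3 of 20 pattern recognition genes passed, and none of the B cell, erythroid, dendritic cell or progenitor markers. At a CPM of 1, 14 of 16 interferon response and 13 of 16 BCL2 family genes passed. High list medians numbered 10 against detected genes and 16 to 17 with 1 sort. The 24 differences from other cell types stayed above 0 with either sort and with a pseudocount of 0.1, but 20 of them were counted as moved in size with that pseudocount. The 10 genes with most reads over both sorts took 10.1% to 16.8%. The genes named for the largest folds each way kept their direction with DESeq2 size factors, total counts, the edgeR exact test and the GC correction. The scalings use the same counts and differ too little to reverse folds of this size, so this was no test of direction. Genes without a matched GC content were left uncorrected. The ratio of Rn45s was the same to every digit before and after, so Rn45s was in effect not corrected. Whether its ratio depends on GC content was therefore not tested. No paired analysis was possible because the design has 1 group. The depth put the limit of 3 reads at a CPM of 0.297 and 0.324, and with 2 libraries no difference between sorts has a replicate check.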

Other observations

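The tests of a mixed library, of small structural RNAs, of the spread of late granule genes, of the primary against the late granule list and of the GC correction were chosen only after the result was seen; the tests of escape genes and of shared Lars2 sequence were set down before. No biological explanation was tested against a group, since the design has only 1.

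Among genes that had no reads in 1 sort and were called by the edgeR exact test, leaving out the sex-linked genes, 5 of 18 overlapped another gene on the same strand, against 5.0% of 1000 sampled genes. One of them, Tnfsf13, chosen after its values were seen, had 0 and 28 reads, while the joint entry BC096441,Tnfsf12 that overlaps it had 64 and 4.

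Xist was read in sort 1 and Y-linked genes in sort 2. A library holding cells of both sexes is argued against, because Xist in sort 2 was 0.0105% of its count in sort 1 and Y-linked genes had 0 reads in sort 1 against 2439 in sort 2. Pools of mice of different sex are the explanation that these counts leave, although the labels give no sex. The median log2 ratio of 4 genes that escape X inactivation, Kdm6a, Ddx3x, Eif2s3x and Kdm5c, was -0.42, at percentile 0.81 of matched random lists. Ddx3x went the other way at 0.22, and after GC correction all 4 were below 0. Sex and sort therefore cannot be separated in any difference between these libraries.

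Rn45s and Lars2 were higher in sort 1. More RNA without a poly(A) tail in that library may account for it, but small structural RNAs gave no decision: 24 of 35 had ratios below 0, with a median at percentile 5.21 of random lists. That percentile became 0.47 after GC correction, and for 33 of these RNAs, with miscellaneous entries left out, it was 6.36 before and 0.84 after that correction, all chosen after the first value was seen. Reads shared between Lars2 and ribosomal RNA also remain open. Lars2 had 0 stretches of 31 bases in common with the annotated transcripts at the Rn45s locus, which had been set down as evidence against sharing, but that bound was wrong because 0 of the 6 transcripts searched were large-subunit ribosomal RNA.

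Genes of both neutrophil lists were abundant despite the CCR3 and SiglecF gate, and the lists moved apart between the sorts. A different share of all neutrophil-lineage cells would move both lists the same way. The primary minus the late granule median was 0.697, outside the range of -0.40 to 0.33 of random pairs. That difference restates the opposite shifts that prompted the test, so it adds no separate evidence. The opposite shifts of the list medians themselves argue against such a share as the whole cause. They do not hold for each late granule gene. Ratios above 0 were found for 3 of 13, among them Retnlg at 0.14 and S100a8 at 0.08, while S100a9 had -0.23. The late granule list took 1.22% of the reads in sort 1 and 1.20% in sort 2. The GC trend is argued against as the cause of the difference between the list medians, since that difference was 0.735 after correction. An admixture of mature neutrophils as the source of the late granule transcripts, led by Retnlg, S100a9 and S100a8, may still apply and cannot be told apart from expression by the sorted cells. The spread of the late granule ratios lay at percentile 63.1 of random lists, which met the bound first set against admixture (the 50th percentile), but that bound was wrong, since genes of neutrophils from different pools may vary as other genes do.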
